A study of Homo sapiens with 3 samples.

How the data were processed

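Total RNA from SW48, an established human colorectal cancer cell line, was profiled on 1-colour arrays with Cy5 dye. There were 3 samples and 3 groups with 1 sample each: cells with the empty vector pcDNA3.1, cells with a plasmid for DDX3 overexpression, and cells with that plasmid and a plasmid for YAP1 knockdown. Per the labels' protocols, cells were kept under G418 for 4 weeks and stable cells were used, and RNA was amplified and labelled with an amino allyl kit. Per the labels, each sample was made from 2 technical replicates. How these were combined is not given in the sources used here, and the values of the separate technical replicates were not analysed here.

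The deposited values are probe intensity on a linear scale, as the range of the values shows. Background correction, scaling between arrays and flags of the authors are not given in the sources used here. The table held 31741 probes in each sample with no missing value. Deposited medians were 469 for the vector, 414 for the DDX3 and 305 for the DDX3+YAPsi library, and the 75th percentiles were 2856, 2495 and 1710, so the samples had not been brought to a common level. The highest values were 647311, 645623 and 621671, and 531, 434 and 238 probes lay above 65535, the ceiling of a 16-bit scan, so the values are not plain scanner readings. Saturation could not be judged from them. The low number of arrays limits the precision of every value.

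For the main setting each sample was multiplied by a factor that brought its 75th percentile to the geometric mean of the 3 samples (0.806, 0.922 and 1.35), and log2 was taken. Without this scaling the array medians differed by -0.18 (log2) for DDX3 against vector, -0.44 for DDX3+YAPsi against DDX3 and -0.62 for DDX3+YAPsi against vector. After it they still differed by 0.01, 0.11 and 0.12. Each difference reported is relative to this scaling, and a rise or fall shared by most genes of a library cannot be seen in it. Since the library named first in each comparison was the dimmer, leaving scaling out lowers every difference, so that small positive ones turn negative and negative ones become more negative.

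Probes were named from the platform annotation, which can be old. Of the 31741 probes, 24658 had 1 gene symbol, 1002 had several and 6081 had none given there. Probes with several or no symbol were left out of gene values. The named probes gave 18282 genes, 5438 of them with 2 or more probes, and a gene took the mean log2 value of its probes. Of the symbols, 16552 were found among current RefSeq symbols (assembly GRCh38.p14, used for names alone). The annotation gave no probe positions, so no coordinates are reported and a probe could not be placed inside or outside a plasmid insert.

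The floor was the 50th percentile of all probes of a sample, at scaled intensities of 378, 382 and 411. A gene counted as measured in a comparison when both values reached the floor, and as higher or lower when the log2 difference was at least 1 (2-fold). Where the brighter library alone reached the floor, the ratio of its value to the other library's floor is given as a lower bound. With 1 sample per group there is no spread between samples, so groups were not tested against each other and no p-value or SD between samples is given. The difference of a gene has no replicate check. For gene lists, 36 of which were written before the data were examined, the median difference was set against 10000 random lists of the same size matched on mean level in 20 bins, and its percentile is given as a description of these libraries. Lists with fewer than 4 measured members have no median.

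A gene stood apart in a library when it differed by at least 1 (log2) in the same direction from both others while these differed by less than 0.5. Genes named in the text follow a rule fixed in advance. It takes, per comparison, the 12 largest increases and 12 largest decreases, the 4 largest bounds in each direction and up to 4 members per list with the largest differences, and 6 genes per library that stands apart and direction. Uncharacterised LOC, ORF and similar clone-based symbols, antisense genes and pseudogenes were passed over, and DDX3X, YAP1 and SIX2 were always included. The text prints part of what the rule allows. The olfactory receptors named together lie partly outside it and are marked as chosen after their values were seen.

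The steps were tested on simulated data for DDX3 against vector with 18282 genes. Of 50 genes changed by each size, 6% of those changed 1.5-fold, 46% of those changed 2-fold, 96% of those changed 3-fold and 100% of those changed 4-fold were called in the right direction, and 9 of 9672 unchanged genes were called. The changed genes were drawn from those with a mean level more than 1.5 (log2) above the floor. Noise had the same SD for all probes of a level bin. The shares called therefore do not cover dimmer genes, several of which are named below. Alternatives were other scalings (median, quantile, loess on mean level with span 0.3), floors at the 25th and 75th percentile and none, thresholds of 1.5-fold and 3-fold, pseudocounts of 1 and 50, the brightest or median probe per gene and 50 level bins. Alternatives chosen after seeing the data were no scaling, a floor on the mean over the samples, and list members entered at their bound. Median centring and no scaling shift all genes of a library alike. They therefore cannot move the percentile of a list or the gap between the medians of different lists. Both are still counted among the alternatives of each list. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.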

Results

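Gene expression was measured with 1 array sample each of SW48 colorectal cancer cells carrying an empty vector, a plasmid for the RNA helicase DDX3, or the DDX3 plasmid together with a plasmid for knockdown of YAP1, the transcriptional coactivator of the Hippo pathway. The design sets the knockdown library against the other libraries, and so asks which differences that come with the DDX3 plasmid are altered when YAP1 is lowered. It holds no library with the knockdown plasmid but without the DDX3 plasmid. An effect of the knockdown plasmid that does not depend on DDX3 therefore cannot be told apart. The libraries were close to each other, with correlations of log2 intensity across probes of 0.994 for DDX3 against vector, 0.993 for DDX3+YAPsi against DDX3 and 0.993 for DDX3+YAPsi against vector. No group had a replicate, so each difference below is between single libraries and was not tested.

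The gene value of DDX3X, the gene of the helicase, was not higher in the libraries labelled with its plasmid, and YAP1 was not lower in the library labelled with the knockdown plasmid. The dimmer DDX3X probe (PH_hs_0028290) had scaled intensities of 1975 in the vector library, 879 in the library labelled DDX3 and 813 in the library labelled DDX3+YAPsi. The brighter probe (PH_hs_0048661) had 49549, 57967 and 48085. Their log2 differences for DDX3 against vector were -1.17 and 0.23, and the gene value over both was -0.47. YAP1, with 1 probe, had 18298, 20279 and 20768, a difference of 0.15 for DDX3 against vector and 0.03 for DDX3+YAPsi against DDX3. Without scaling that last value was -0.51, beside a shift of the array medians of -0.44. Because the gene value of neither DDX3X nor YAP1 bears out the labels, the libraries are called the library labelled DDX3 and the library labelled DDX3+YAPsi. Probe positions were not given, so a DDX3X probe outside the plasmid insert would check nothing.

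**Figure D1:**
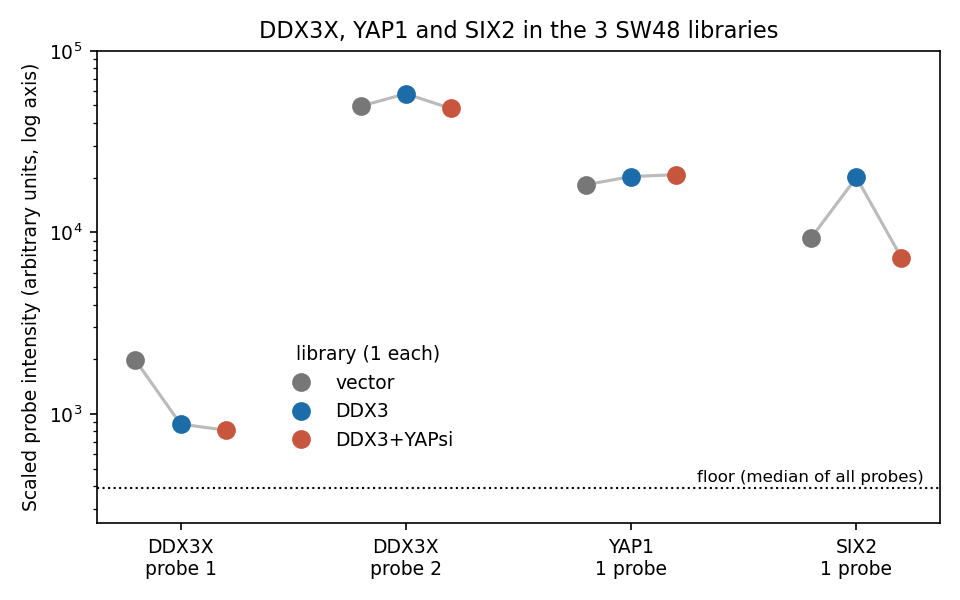
Scaled probe intensity on a log axis for the probes of DDX3X, YAP1 and SIX2, with 1 point per library (vector, DDX3, DDX3+YAPsi) and the floor as a dotted line. SIX2 had 9353, 20057 and 7243, while YAP1 stayed between 18298 and 20768.

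SIX2, a homeobox transcription factor and the factor the study followed, was 2.14-fold higher in the library labelled DDX3 than in the vector library (log2 difference 1.10) and 2.77-fold lower in the library labelled DDX3+YAPsi than in the library labelled DDX3 (-1.47). Among measured genes it ranked 11 from the highest of 9863 and 3 from the lowest of 9834. Against the vector library the library labelled DDX3+YAPsi differed by -0.37. The value rests on 1 probe, and without scaling the difference of DDX3 against vector was 0.91, below the 2-fold threshold. Both directions depend on labels that DDX3X and YAP1 did not bear out. Of the homeobox family of SIX2 and its EYA partners, 3 of 10 genes on the array were measured, and SIX5 differed by -0.38 and 0.66 in these comparisons.

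Between the library labelled DDX3 and the vector library, immediate early genes and YAP/TAZ targets were higher. All 17 immediate early genes were measured and 16 lay above 0, with a median of 0.38, above all 10000 random lists. ATF3, a stress-responsive transcription factor, was 2.59-fold higher (1.37), JUN differed by 0.76, KLF2 by 0.73 and ZFP36 by 0.68. The member below 0 was MCL1, an apoptosis inhibitor that is also on the list of apoptosis regulators, at -0.62. Of the YAP/TAZ target signature 13 of 22 genes were measured, 12 of them above 0, with a median of 0.36 at the 99.99th percentile. CYR61, a secreted matrix protein and a textbook YAP target, was at 1.05, GADD45A at 0.71, MYOF at 0.69 and ASAP1 at 0.63. CYR61, the 1 member past 2-fold, rests on 1 probe and had 417 in the vector library, near the floor of 378 there. MAPK feedback and output genes had a median of 0.21 at the 99.8th percentile, with 11 of 14 measured genes above 0. FOSL1, a subunit of the AP-1 transcription factor, was 2.28-fold higher (1.19), and DUSP6, a phosphatase that acts on ERK, differed by 0.57. FOSL1 also rests on 1 probe and had 479 in the vector library. With a floor at the 75th percentile the MAPK list was at the 94.9th percentile. Without scaling the medians of the immediate early, YAP/TAZ and MAPK lists were 0.18, 0.16 and 0.02.

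In the same comparison, translation initiation factors had a median of 0.13 at the 99.4th percentile, with 19 of 26 above 0, which was -0.07 without scaling. The list fell inside the range of random lists with the brightest probe (97.4). Lipogenesis genes had a median of -0.19 at the 1.61st percentile with 9 of 13 below 0, including ACACA at -0.53 and SREBF1 at -0.52, and the list kept its place in 9 of 15 alternatives and moved to the 58.2nd percentile with the brightest probe of each gene. Cholesterol synthesis genes lay at -0.15 and the 2.98th percentile, with MVK, a kinase of the mevalonate pathway, at -0.73, and kept their place inside the range of random lists in 11 of 15 alternatives, with a lowest percentile of 0.885. EGF receptor family genes lay at 0.24 and the 97.2nd percentile, with HBEGF at 0.47, and kept theirs in 10 of 14, with a highest percentile of 98.8. Without scaling the EGF receptor median was 0.05. Wnt targets (0.02), Hippo pathway components (0.05), epithelial junction genes (0.02), mesenchymal genes (-0.05), G1/S genes (0.05) and G2/M genes (-0.02) had medians inside the range of 95% of random lists.

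In all, 18 genes were at least 2-fold higher and 15 at least 2-fold lower among 9863 measured in both the library labelled DDX3 and the vector library. The highest was OPTC, an extracellular matrix proteoglycan, at 1.74, followed by the olfactory receptor OR51Q1, which was 2.82-fold higher, the cell cycle kinase CDK6 at 1.49 with probes at 0.96 and 2.01, and the adaptor SH2B2, which was 2.78-fold higher. The chemokine CCL8 (1.17), the scavenger receptor COLEC12 (1.14), the Wnt agonist RSPO2 (1.12) and the aminopeptidase RNPEP (1.06) were also among the 12 highest. ISYNA1, the enzyme of inositol synthesis, was 9.02-fold lower (-3.17), with intensities of 615 against 5545. Lower values were also found for MRPL38, a mitochondrial ribosomal protein (-1.98), the splicing factor RBM4B (-1.62), the natriuretic peptide receptor NPR2 (-1.45), GLIS1 (-1.41), GMPPA (-1.37), the calcium sensor NCS1 (-1.16) and the growth factor MDK (-1.09). POU3F1, a transcription factor below the floor in the vector library, was at least 4.69-fold higher, and REG3G, below the floor in the library labelled DDX3, was at least 3.16-fold lower. Apart from CDK6, each gene named in this paragraph rests on 1 probe. Without scaling the split was 6 higher and 45 lower, and the floor and the threshold moved both counts by over 1.5 times.

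Between the library labelled DDX3+YAPsi and the library labelled DDX3, the YAP/TAZ target signature had no common direction. Its median over 13 measured genes was 0.07 at the 56.9th percentile, with 7 above 0 and 6 below. CYR61 was at -0.56, NT5E at -0.35, NUAK2 at 0.41 and ARHGEF17 at 0.40. Without scaling that median was -0.48, beside the shift of the array medians of -0.44. Hippo pathway components lay at 0.18 and the 92.8th percentile, with 12 of 17 above 0, TEAD3 at 0.45 and MOB1A, a kinase activator of the pathway, at -0.67, and reached the 98.9th with the brightest probe.

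Other lists lay outside the range of 95% of random lists in this comparison. Immediate early genes had a median of 0.27 at the 99.7th percentile with 14 of 17 above 0, led by EGR1 at 0.82. MAPK output genes had 0.24 at the 99.1st percentile with 11 of 14 above 0, although DUSP6 was at -0.88, and Wnt targets had 0.20 at the 98.3rd percentile with 15 of 16 above 0, including SOX9 at 0.53. Without scaling these 3 medians turned to -0.28, -0.31 and -0.34. The Wnt list stayed outside the range in 9 of 15 alternatives, with a lowest percentile of 91.2. Mitotic genes had a median of -0.18 at the 0.865th percentile, with 20 of 25 below 0, among them the spindle checkpoint kinases BUB1 (-0.67), BUB1B (-0.62) and TTK (-0.61). Oxidative phosphorylation genes had -0.14 at the 1.76th percentile with 19 of 25 below 0, led by SDHD at -0.87 and COX7B at -0.67, and fell inside the range with a floor at the 75th percentile (2.96). Translation initiation factors had -0.15 at the 1.27th percentile with 18 of 26 below 0. This list was at the 99.4th percentile in DDX3 against vector and at a median of 0.01 in DDX3+YAPsi against vector. The fall and the earlier rise share the library labelled DDX3, so a deviation of that library alone cannot be told apart from a return. Common reference genes had -0.23 at the 0.71st percentile with 9 of 12 below 0, including GAPDH at -0.63, while POLR2A was at 0.59. The MAPK list fell inside the range with a floor at the 25th percentile (95.1) or none (94.8) and with the brightest probe (97.2), and the immediate early list did so with a floor at the 75th percentile (96.5).

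At the 2-fold threshold, 11 genes were higher and 16 lower of 9834 measured in the libraries labelled DDX3+YAPsi and DDX3. OPTC was 3.51-fold lower (-1.81), POU3F1 3.37-fold lower (-1.75) and the splicing factor SRSF7 lower by a log2 difference of -1.32. The phospholipase PLA2G2E (-1.25), GMFB (-1.21), the mitochondrial ribosomal protein MRPL47 (-1.13), the chromatin protein MORF4L2 (-1.13) and the ubiquitin hydrolase UCHL3 (-1.12) were lower as well. FAM167B was 3.27-fold higher (1.71), the RNA-binding protein MSI1, a stem cell marker, 2.47-fold higher (1.31), and FBLL1 2.41-fold higher (1.27). In the library labelled DDX3, FAM167B and MSI1 had intensities of 397 and 461, near its floor of 382. NCS1 was at 1.16 and ISYNA1 at 1.01, each opposite to its difference between the library labelled DDX3 and the vector library. OPTC, POU3F1, SRSF7, MORF4L2, FAM167B, MSI1, FBLL1, NCS1 and ISYNA1 each rest on 1 probe. The largest gene value was DIP2C at 2.43, but its probes stood at -0.025 and 4.89, and the brightest probe was the former. AK5, an adenylate kinase, was at least 3.15-fold higher, and BMPR1A, a BMP receptor, at least 2.46-fold lower. Without scaling 3 genes were higher and 556 lower.

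Between the library labelled DDX3+YAPsi and the vector library, immediate early genes had a median of 0.60, with 16 of 17 above 0 and ATF3 (1.75) and EGR1 (1.26) above 2-fold. The YAP/TAZ target signature had a median of 0.49 with 11 of 13 measured genes above 0, including CTGF at 0.84, ASAP1 at 0.77 and F3 at 0.69. MAPK output genes had a median of 0.45 with 10 of 14 above 0, with FOSL1 at 1.06 and PHLDA1 at 0.69. None of the 10000 random lists lay above these medians, yet without scaling they were -0.14, -0.25 and -0.29, beside a shift of the array medians of -0.62. The YAP/TAZ list was at the 89.7th percentile with no floor. CTGF and FOSL1 each rest on 1 probe and had 476 and 479 in the vector library, where the floor was 378. Immediate early and MAPK lists share 2 genes, EGR1 among them, and the YAP/TAZ list shares no gene with either.

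**Figure D2:**
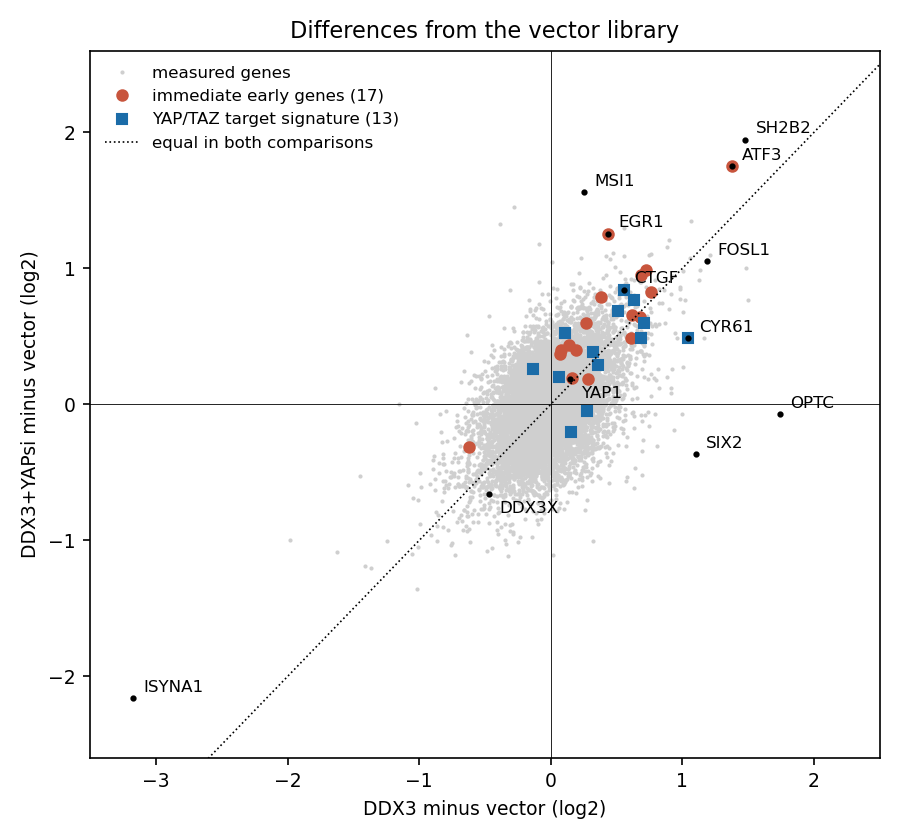
Log2 difference from the vector library of the library labelled DDX3 (horizontal) and of the library labelled DDX3+YAPsi (vertical), with 1 grey point per measured gene, immediate early genes as circles, YAP/TAZ targets as squares and a dotted line of equal difference. Medians of the immediate early genes were 0.38 and 0.60, and without scaling the second of these was -0.14.

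In this last comparison Wnt targets had a median of 0.29 at the 99.9th percentile with 11 of 16 above 0, although TNFRSF19 was at -1.03, and TGF-beta targets had 0.23 at the 98.0th percentile, with SMAD6 at 0.79. Both turned without scaling, to -0.45 and -0.51. Hippo pathway components had 0.22 at the 96.2nd percentile, inside the range of random lists there and in 12 of 15 alternatives, with a highest percentile of 99.7. The TGF-beta list stayed outside the range of random lists in 7 of 15 alternatives, with a lowest percentile of 91.2, and the Wnt list in 14 of 15. Mitotic genes had -0.18, below the 2.5th percentile, though with a floor at the 75th percentile (2.58) or loess centring (2.83) they were above it. Common reference genes had -0.33 at the 0.1st percentile, with GAPDH at -0.73 and PPIA at -0.45, while POLR2A was at 0.76 and YWHAZ at 0.45. Cholesterol synthesis genes were at -0.19 and the 2.84th percentile, with FDPS at -0.76, and stayed inside the range in 10 of 15 alternatives. Translation initiation factors (0.01), oxidative phosphorylation genes (-0.12), cytosolic ribosomal proteins (-0.14), heat shock genes (-0.12) and p53 targets (0.11) lay inside the range of 95% of random lists.

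Of 9855 genes measured in both, 27 were at least 2-fold higher and 20 lower in the library labelled DDX3+YAPsi than in the vector library. SH2B2 was 3.85-fold higher (1.95), LINC00520 3.28-fold (1.71), MSI1 2.95-fold (1.56), RNPEP 2.55-fold (1.35), FAM167B 2.51-fold (1.33), and SAPCD2 2.46-fold higher (1.30), and MEX3D, an RNA-binding protein, was at 1.32. In the vector library LINC00520 and MSI1 had intensities of 379 and 386, close to its floor of 378. NFATC2, a T cell transcription factor, had the largest value at 2.33, but its probes stood at 0.25 and 4.42. ISYNA1 was 4.47-fold lower (-2.16), OR10AD1 2.56-fold (-1.36), GMPPA 2.31-fold (-1.21), GLIS1 2.29-fold (-1.19), topoisomerase TOP1 2.15-fold (-1.11) and the proteasome subunit PSMD4 2.08-fold lower (-1.06). Apart from NFATC2, each gene named in this paragraph rests on 1 probe. With centring on the median the split was 14 higher and 44 lower, and without scaling 3 and 1892.

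**Figure D3:**
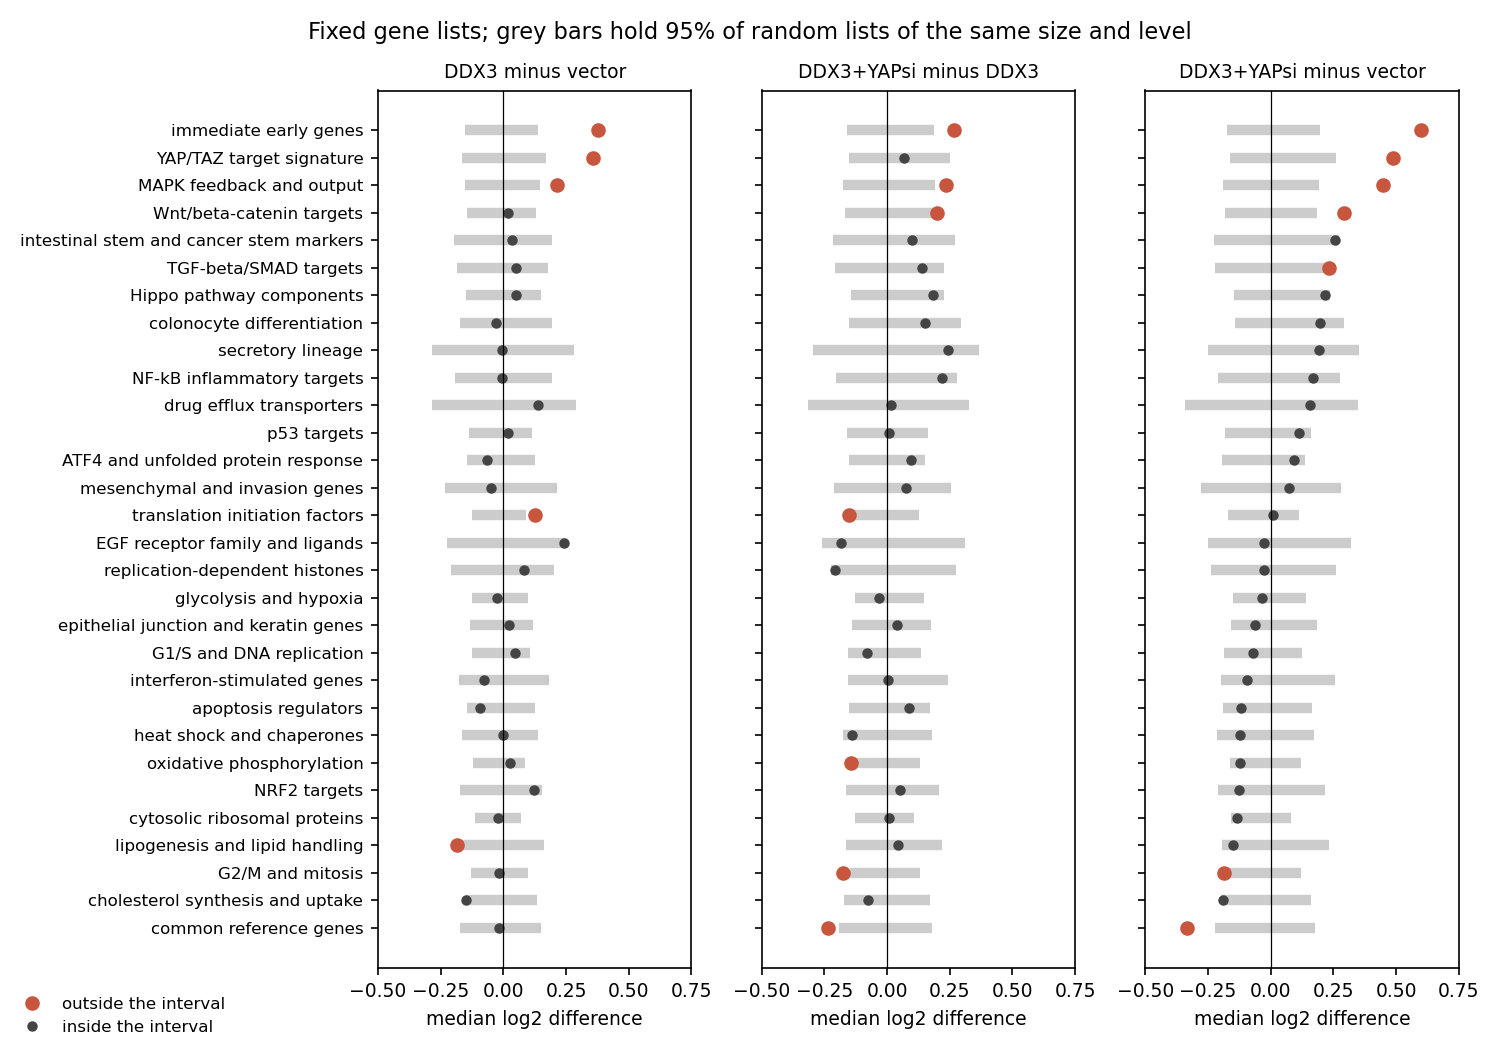
Median log2 difference of each of 30 gene lists in the 3 comparisons, with grey bars for the range of 95% of random lists and larger red points outside it. Outside lay 5, 7 and 7 lists, where lists of unrelated genes would give 1.5, and lists whose genes vary together would give more. Without scaling the positive medians of both comparisons with the library labelled DDX3+YAPsi turned negative.

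Of the 18 genes at least 2-fold higher in the library labelled DDX3 than in the vector library, 14 moved back by any amount in the library labelled DDX3+YAPsi. OPTC and SIX2 moved back by at least 2-fold, and 7 stayed at least 2-fold above the vector library, among them ATF3, CDK6, FKBPL, FOSL1, RNPEP and SH2B2. Of the 15 lower genes, 12 moved back by any amount, ISYNA1 and NCS1 by at least 2-fold, and 8 stayed at least 2-fold below. The median share of the difference retained was 78.1% for the higher and 68.1% for the lower genes, where simulated noise alone gives 50% and 49.6%. These simulated shares are those of equal noise in all libraries, and unequal noise would give others, so the gap is no measure of a retained effect. Among 9728 genes measured in all 3 libraries, the vector library stood apart for 13, the library labelled DDX3+YAPsi for 7 and the library labelled DDX3 for 3, against a mean of 7.53 with the values of each gene permuted (95% of permutations between 3 and 12). These 3 were OPTC and SIX2, higher, and NCS1, lower.

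In both the libraries labelled DDX3 and DDX3+YAPsi, 7 genes were at least 2-fold higher and 8 at least 2-fold lower than in the vector library. None went opposite ways, which decides nothing, since so few called genes with a shared vector library would hardly give such a gene. Independent lists would share 0.046 and 0.031 genes, and simulated unchanged libraries with a shared vector library share 0.19 and 0.1. That simulated noise put a mean of 6.965 genes at least 2-fold apart, where DDX3 against vector had 18 higher and 15 lower. Fewer called genes leave less room for sharing, so the simulated values may be too low for noise in these arrays. Part of the excess may come from the shared vector library, which cannot be split. Across 10098 genes, which are not independent replicates, the difference of DDX3 against vector correlated with that of DDX3+YAPsi against DDX3 at r = -0.39, where simulated unchanged libraries give -0.50, and their covariance was -0.0336 against a simulated -0.0424. With the difference of DDX3+YAPsi against vector r was 0.48, where the simulation gives 0.50, and the covariance was 0.0441 against 0.0423. The simulated r is what equal noise in all libraries gives. Across genes the differences had SDs of 0.27 for DDX3 against vector and 0.30 for DDX3+YAPsi against DDX3. For DDX3+YAPsi against vector the SD was 0.32. These SDs largely fix both r values, so the gaps from the simulation decide nothing about the knockdown.

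Marker genes of other cell types were mostly below the floor. Of 10 fibroblast genes 1 was measured in DDX3 against vector, COL1A1, and of 9 leukocyte genes on the array 2 were, CD14 and CD68. Endothelial markers and the markers of kidney, liver and neural lines had 1 measured gene each, and the highest intensity of the latter in any library was 565.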

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

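Chosen only after the result was seen were the tests of exchanged labels, scaling, probe position, stress responses and the vector library standing apart. Those of a probe-specific artefact and of an error in the DDX3 array were chosen before. The rules that at least 6 further probes, and at least 80% of list members within 0.25 (log2), are needed before a test counts in favour of an explanation were both added after the values were seen. Without them the probe-specific artefact and, for YAP/TAZ targets, the vector library standing apart would each have counted as having the values they need. The readings of 3 more tests were also set after their values were seen. Scaling and stress responses had been read as excluded and the error in the DDX3 array as having the values it needs, and all 3 were then left open. A heat shock response was next read as excluded by a rule of its own. The same rule now applies to all the stress responses and must hold in every alternative, which leaves each of them open.

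Probes without a single gene symbol, which enter no gene value of the report, also differed. In the library labelled DDX3, 11 of 2274 such measured probes were at least 2-fold higher than in the vector library (0.484%, against 0.251% of probes with 1 symbol), and in the library labelled DDX3+YAPsi 14 of 2296 were (0.61%, against 0.397%). The probes PH_hs_0011913 (1.03 and 1.46) and PH_hs_0036173 (1.11 and 1.40) were higher in both. Lower probes made up 0.529% against 0.221% in DDX3+YAPsi against DDX3, a wider gap, and 0.396% against 0.243% in DDX3 against vector. Shares were closer for lower probes in DDX3+YAPsi against vector (0.392% against 0.382%). Higher probes in DDX3+YAPsi against DDX3 made up 0.264% against 0.221%.

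The gene value of DDX3X was not higher and YAP1 not lower in the libraries named for them. If the YAP1 probe reads a working knockdown, an exchange of labels among the 3 libraries needs a library with clearly low YAP1. The lowest lay 0.148 (log2) below the next, so no order of the labels shows a knockdown at this probe. Where the knockdown is absent or the probe does not read it, this value cannot tell the labels apart, and an exchange stays open. Scaling by 1 factor per library leaves ranks as they are, so the 51.8th percentile of YAP1 among measured genes for DDX3+YAPsi against DDX3 decides nothing about scaling, and a fall shared by most genes stays open. Probe position stays open too, because the DDX3X probes differed from each other by 1.39 (log2) for DDX3 against vector and their place relative to the insert is not given. Loss of the constructs or an effect on protein alone was not tested.

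Immediate early and YAP/TAZ target lists were higher in the libraries labelled DDX3 and DDX3+YAPsi than in the vector library. A vector library that stands apart alone would leave both lists unmoved between the other libraries, but the immediate early list was at the 99.7th percentile there. It stayed outside the range of random lists in 14 of 15 alternatives, and was inside it with a floor at the 75th percentile (96.5). Median centring and no scaling are among these alternatives but cannot move the percentile of a list. A vector library that stands apart together with a further difference between the other libraries stays open. For YAP/TAZ targets a vector library that stands apart alone stays open, with the list at the 56.9th percentile and 7 of 13 members within 0.25. A probe-specific artefact stays open too, with 4 further probes whose medians of 0.16 and 0.30 lay at the 81.1st and 95.2nd percentile, inside the range of random probes. A heat shock response would raise chaperone genes by about as much, but the 75th percentile of 12 measured members was 0.185 (log2) in DDX3 against vector and 0.02 in DDX3+YAPsi against vector, where the lists had medians of at least 0.36 and 0.49; the median fell short by more than the members' interquartile range in both comparisons in 11 of 13 alternatives, but not with a floor at the 25th percentile or none, so it stays open. An unfolded protein, p53 or NF-kB response stays open too: the lower of both percentiles against the vector library was at most 66.6, and NF-kB targets had a median of -0.01 and quartiles of -0.05 and 0.02 in DDX3 against vector, with 6 of 9 below 0, short in 11 of 12 alternatives, but in DDX3+YAPsi against vector their quartiles were 0.03 and 0.37, the unfolded protein list was at 93.6 and p53 targets at 92.6. An effect of DDX3, and handling of a single culture per group, remain untested.

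SIX2 was higher in the library labelled DDX3 than in both other libraries. Genes that peak or dip at least 2-fold in that library numbered 4, against 15 in the vector library and 7 in the library labelled DDX3+YAPsi. The reading fixed beforehand, that an error in the DDX3 array would make such genes no more frequent there, was wrong, since an error across the array would add them. The count gives no sign of such an error, and an error at the single SIX2 probe stays open, as does a response of SIX2 to the plasmids.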

How the results depend on the processing

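Settings chosen after the data were seen were no scaling, a floor on the mean over the samples, and list members entered at their bound. No paired analysis was possible because each group has 1 sample, and leaving out a replicate was not possible for the same reason. Signal over the floor limits which genes can be counted. Of 126 counts under alternatives 64 stayed within 1.5 times the main count. Of 97 differences of named genes past the 2-fold threshold, 68 stayed past it without scaling, 84 with a pseudocount of 50 and 89 with the brightest probe. The cause of the changes below was not tested, except that floors and thresholds change which genes can be counted.

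Counts are given as higher and lower for DDX3 against vector, DDX3+YAPsi against DDX3, and DDX3+YAPsi against vector, then as genes where the vector, DDX3 or DDX3+YAPsi library stood apart. With a floor at the 25th percentile they were 47 and 31, 40 and 30, and 64 higher, with 20, 11 and 22 apart. With a floor at the 75th percentile they were 3 and 5, 1 and 6, and 7 and 6, with 3 apart for vector and 0 for DDX3+YAPsi. With no floor they were 78 and 37, 51 and 51, and 89 and 37, with 26, 20 and 31 apart. At 1.5-fold they were 171 and 183, 239 and 246, and 335 and 287, with 143, 46 and 125 apart, and at 3-fold 1 and 3, 3 and 2, and 4 and 1, with 0, 1 and 0 apart. The brightest probe gave 29, 26 and 49 higher, with 5 apart for DDX3 and 16 for DDX3+YAPsi. No scaling gave 6 and 45, 3 and 556, and 3 and 1892, with 35 apart for vector and 388 for DDX3+YAPsi. A floor on the mean gave 28 and 19 higher in the comparisons that involve the DDX3 library, with 5 apart for DDX3 and 13 for DDX3+YAPsi. Median centring gave 14 and 44 for DDX3+YAPsi against vector.

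SIX2, at 1.10 and -1.47, did not reach 3-fold, and without scaling it was 0.91 for DDX3 against vector and -1.11 for DDX3+YAPsi against vector. DDX3X in DDX3+YAPsi against vector, at -0.66, passed 1.5-fold, and was -1.40 without scaling. MAPK output genes in DDX3+YAPsi against DDX3 fell inside the range of random lists with a floor at the 25th percentile (95.1), no floor (94.8) and the brightest probe (97.2), and in DDX3 against vector with a floor at the 75th percentile (94.9). Immediate early genes in DDX3+YAPsi against DDX3 did so with that floor (96.5), and YAP/TAZ targets in DDX3+YAPsi against vector with no floor (89.7). With the brightest probe the lipogenesis list of DDX3 against vector moved to the 58.2nd percentile and DIP2C reversed to -0.025 in DDX3+YAPsi against DDX3 and -0.092 in DDX3+YAPsi against vector.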

Other observations

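At the main setting, lists of cell identity and of stress lay inside the range of 95% of random lists in each comparison. Some left it under an alternative: NRF2 targets in DDX3 against vector, at 0.12 and the 94.8th percentile (-0.07 without scaling), kept their place in 9 of 15 alternatives and reached the 98.9th, heat shock genes in DDX3+YAPsi against DDX3 reached the 1.1st percentile, and apoptosis regulators the 0.32nd in DDX3 against vector and the 0.27th in DDX3+YAPsi against vector. Secretory lineage genes reached the 98.99th percentile in DDX3+YAPsi against DDX3, stem markers the 1.0th in DDX3 against vector and NF-kB targets the 98.4th in DDX3+YAPsi against vector. Intestinal stem and cancer stem markers had a median of 0.26 at the 96.4th percentile in DDX3+YAPsi against vector, with 7 of 9 measured genes above 0 and MSI1 at 1.56, while ALDH1A1 was at -0.77, and without scaling the median was -0.48. Colonocyte differentiation genes had 0.20 at the 84.9th percentile and secretory lineage genes 0.19 at the 80.5th in that comparison, and without scaling both turned, to -0.54 and -0.55. In DDX3+YAPsi against vector interferon-stimulated genes had -0.09, NF-kB targets 0.17, NRF2 targets -0.13, the ATF4 and unfolded protein response list 0.09, glycolysis and hypoxia genes -0.03, apoptosis regulators -0.12, drug efflux transporters 0.16 and replication-dependent histones -0.03. Of the efflux transporters ABCC4 was at 0.63 in DDX3 against vector and 0.92 in DDX3+YAPsi against vector.

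Olfactory receptor genes, a family chosen after the values were seen, made up 75 of 9863 measured genes in DDX3 against vector (0.76%) but 2 of the 33 genes past 2-fold (6.06%), OR51Q1 and OR10AD1. In DDX3+YAPsi against DDX3 they were 2 of 27 (7.41%), OR1J4 and OR2T1, and in DDX3+YAPsi against vector 2 of 47 (4.26%), OR10AD1 and OR11G2. Their median intensity was 890 in DDX3 against vector, where all measured genes had 2399, and the SD of their differences across genes was 0.37, against 0.27 for all measured genes.

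Probes of the same gene seldom moved together past the threshold. Of 2371 genes with at least 2 measured probes in DDX3 against vector, 22 had a probe past 2-fold and 0 had both, and the correlation between probes across genes was 0.29. The other comparisons gave 14 and 39 such genes with 0 and 0 for both probes, and correlations of 0.43 and 0.35.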
